A study of Homo sapiens with 16 samples.

How the data were processed

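RNA immunoprecipitation was profiled on single-colour Illumina expression arrays in HepG2 cells, an established human hepatocarcinoma line. Per the labels' protocols, cells were kept for 30 min in regular medium or in medium with 10 µM β-lapachone. Cytoplasmic lysate was then precipitated with a mouse antibody against NQO1 or with mouse IgG, the negative control for RNA that binds to beads or antibody without NQO1. RNA from the precipitates was amplified from an oligo-dT primer and labelled with biotin, per the labels' protocols, so that the arrays read polyadenylated RNA. The labels gave 4 groups of 4 arrays, and each array was assigned to its group and replicate number by its title. Nothing in the labels said whether the 4 replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

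One table of 47231 probes was used. The intensity of each probe was deposited on a linear scale, and per the file headers each intensity column is followed by a detection p-value for the same array. The table was deposited under a name that calls its values not normalized. GenomeStudio 2011.1 is named in the submitters' processing notes, and its settings are not given in the sources used here. The lowest intensity of every array lay between 73.1 and 118, and the arrays differed in every summary of intensity looked at, as values not normalized between arrays would. The deposited detection p-value fell with intensity within each array (Spearman correlation across probes between -0.999 and -0.995). No 2 arrays held identical values.

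The table identifies probes by manufacturer ID only. The gene table used for names held 0 of these IDs, so the files do not pair probes with genes, and no probe was named. The design had planned 1 probe per named gene, 2 genes followed in every comparison (SERPINA1 and NQO1) and tests of gene lists fixed in advance. These were not analysed here, and the unit of every test became the single probe. The IDs of 4 probes are printed, 2 with higher and 2 with lower values.

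Intensities were corrected by the normexp model fitted from the detection p-values, offset by 16, quantile normalized and put on the log2 scale with neqc in limma 3.58.1 under R 4.3.3. A probe was called detected on an array at a detection p under 0.05, and the 19914 probes detected on at least 4 of the 16 arrays were tested. One linear model with a mean for each of the 4 groups was fitted to all 16 arrays with limma's lmFit and eBayes. It gave 6 comparisons: NQO1 against IgG in control medium, after β-lapachone and averaged over both, the difference of that ratio between media, and β-lapachone against control medium within each precipitate. P-values were adjusted by Benjamini-Hochberg over the probes of each comparison, with a threshold of 0.05. The probes described were the 5 with the smallest p in each direction, the rule set before the data were examined for a comparison with fewer than 3 calls. These are values, not calls. A probe not detected on any array of a group has only a bound there. Its fold is the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among detected probes of that array, and is written as "at least". Such a bound holds for the main processing only.

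The normalization, background correction, detection filter, arrays in the fit, array weights, a block for the replicate number and the omission of each array in turn were varied as alternatives chosen before the data were examined. Fits restricted to arrays with many detected probes, or with covariates, were chosen after seeing the data. The covariates were the number of detected probes, the first 1 to 4 principal components of the 16 arrays, and the first 1 to 3 components of the deviations from the group means. The fit with 2 components of the 16 arrays was singled out after the counts of all 7 component settings had been seen. Array measures were compared between groups by exact permutation tests, two-sided, with Benjamini-Hochberg adjustment over the 12 tests of the family.

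The fit was tested before use on simulated arrays and on the real arrays with known changes put in, and the latter are given here. In each of the 4 comparisons of 2 groups, 200 of the 19914 probes were changed by a known fold. The changes were added to the normalized log2 values, so any shrinking of a change near background is not included. No 2-fold change was recovered. Of the 4-fold changes, 23.0% were recovered for NQO1 against IgG in control medium, 19.0% after β-lapachone, 17.0% for β-lapachone in the NQO1 precipitate and 20.5% in the IgG precipitate. Of the 8-fold changes, 55.0%, 54.0%, 54.5% and 66.5% were recovered in the same order. The number of arrays and the spread between them limit the precision. The 95% confidence interval of a 2-group difference reached a median of 1.26 to either side on the log2 scale, or 2.39-fold.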

Results

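The study asked which RNAs associate with NQO1, a cytosolic enzyme that reduces quinones, in HepG2 hepatocarcinoma cells, and whether β-lapachone, a quinone that NQO1 reduces, changes that association. RNA bound to an anti-NQO1 antibody or to control IgG was measured on 16 arrays, 4 for each combination of antibody and medium. Of 47231 probes, 27343 were detected on at least 1 array and 5791 on all 16. The probes carry no gene names in the files, so levels of SERPINA1 and NQO1 mRNA and of the gene groups planned were not analysed here.

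The arrays differed widely in the number of detected probes within each group. IgG precipitates from control medium gave 16245 ± 1863.7 detected probes (mean ± SD, n = 4) and those from β-lapachone-treated cells 14221 ± 3922.9 (n = 4). NQO1 precipitates gave 14872 ± 4149.2 in control medium (n = 4) and 17168 ± 2748.6 after β-lapachone (n = 4). The lowest number, 9101, was on replicate 4 of the NQO1 precipitates in control medium, and the highest, 19097, on replicate 4 of the NQO1 precipitates after β-lapachone. The difference between NQO1 and IgG precipitates was 2947.8 detected probes after β-lapachone and -1372.5 in control medium, and neither exceeded the larger SD of the groups compared. None of the 12 comparisons of detected probes, of the share of intensity in the 100 brightest probes or of the first principal component between groups passed the threshold. The smallest adjusted p-value among them was 0.735 by the exact permutation test. With 4 arrays against 4 this test cannot go below an unadjusted p of 0.0286, so that 7 of the 12 comparisons would have to reach it before any passed, and a difference in a single comparison could not pass.

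**Figure D1:**
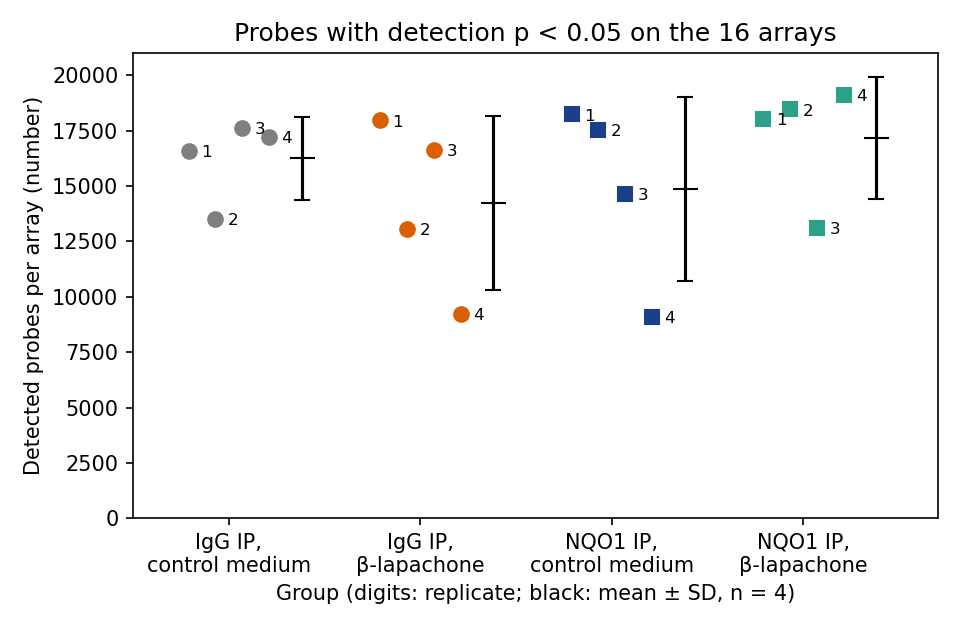
Number of probes detected per array (vertical axis, from 0) for the 4 groups (horizontal axis), with 1 point per array labelled by its replicate number and the mean ± SD of 4 arrays in black. Each group holds an array of 14638 probes or fewer, and the 4 ranges share the stretch from 13524 to 17632.

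After normalization the first principal component held 67.2% of the variance between arrays and the second 16.2%. The 4 groups accounted for 11.7% of the first and 9.59% of the second. Pairs of single arrays of the same group correlated at a median r of 0.800 (0.495 to 0.994). Pairs of different antibody and the same medium had a median of 0.865, so arrays resembled their own replicates no more than those. On the 10 arrays with over 16000 detected probes, picked after seeing the data, the medians were 0.975 and 0.948.

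**Figure D2:**
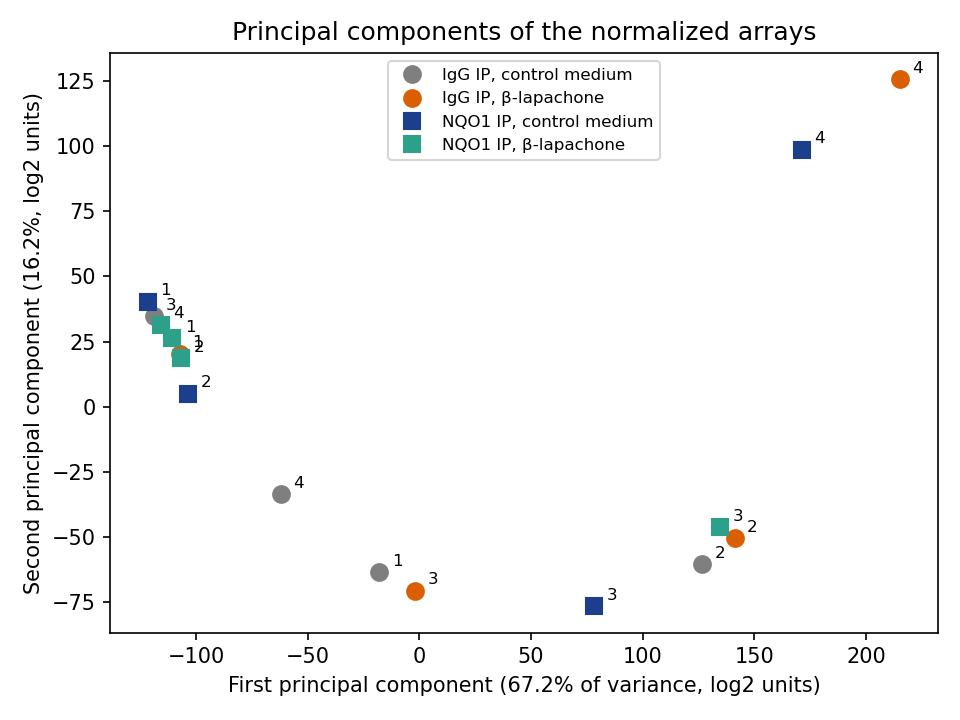
Scores of the 16 arrays on the first principal component (horizontal axis, 67.2% of variance, log2 units) and the second (vertical axis, 16.2%), coloured by group and labelled by replicate number. Arrays of all 4 groups lie on both sides of 0 on the first component, from -122 to 215.

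The first comparison asked which RNAs were enriched by the anti-NQO1 antibody over IgG in control medium. The mean profiles of the 2 precipitates correlated at r = 0.978 across 19914 probes. No probe passed limma's test. Array weights gave 4740 calls, but 21 of the 35 splits of the same arrays into 2 groups gave as many. An unadjusted p under 0.05 was reached by 59 probes, where 996 would be expected by chance on average, and the smallest adjusted p was 1. Many probes moved together along the first principal component. Single counts can therefore lie far from 996, and no conclusion is drawn from the shortfall. Leaving out 1 array moved the 59 to between 29 (without IgG replicate 1 in control medium) and 340 (without NQO1 replicate 3 in control medium), and by over 1.5 times for 7 of the 16 arrays. Of the 5 leading probes with higher values in the NQO1 precipitate, 3 were not detected on any IgG array and have only a bound. The other 2 lay 1.17 and 1.39 above IgG on the log2 scale, with SE 0.41 and 0.46. The 5 leading probes with lower values had log2 differences from -1.31 to -0.81, with SE 0.28 to 0.38. All 4 NQO1 arrays lay above or below all 4 IgG arrays for 129 probes, or 0.648% of those tested, where chance gives 2.86% on average, with the same limit. Detection on all 4 NQO1 arrays and no IgG array was found for 1 probe, and the opposite for 11. However, 7079 probes were detected on all 4 NQO1 arrays and 10976 on all 4 IgG arrays. The counts of 1 and 11 cannot be told apart from that difference.

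After β-lapachone the mean profiles of the NQO1 and IgG precipitates correlated at r = 0.927 across probes. In the fitted means, which include probes near background, 2803 probes were at least 2-fold higher and 1568 at least 2-fold lower in the NQO1 precipitate than in IgG, against 183 and 545 in control medium. These counts went with single arrays and with the scaling. After the drug the mean score on the first principal component was 61.8 in IgG and -49.6 in NQO1 precipitates, against -18.1 and 5.99 in control medium, and IgG replicate 4 had only 9223 detected probes. Without that array, 1314 probes were at least 2-fold higher and 80 at least 2-fold lower, and without NQO1 replicate 3 after β-lapachone 4314 and 3410. In control medium the counts were 363 and 11 without NQO1 replicate 4, and 961 and 1837 without NQO1 replicate 2. Median centring turned the balance after the drug to 1451 higher and 1972 lower, with the median of all probes at -0.38 in place of 0.03. In control medium, scaling each array by its z score turned the balance to 203 higher and 25 lower, while median centring kept it at 99 and 244. No probe passed limma's test, 146 reached an unadjusted p under 0.05 and the smallest adjusted p was 0.729. Leaving out 1 array moved the 146 to between 52 (without NQO1 replicate 1 after β-lapachone) and 1881 (without NQO1 replicate 3 after β-lapachone), on either side of the 996 expected by chance, and by over 1.5 times for 8 arrays. Array weights gave 8896 calls, a count that 11 of the 35 splits of the same arrays reached. The 5 leading probes with higher values lay 0.70 to 2.02 above IgG on the log2 scale, and 4 of the 5 with lower values had differences from -1.78 to -0.82, while 1 was not detected on any NQO1 array. The groups did not overlap for 172 probes, or 0.864%. Detection on all 4 NQO1 arrays and no IgG array was found for 19 probes, and the opposite for 5. Here 11070 probes were detected on all 4 NQO1 arrays and 7222 on all 4 IgG arrays. The counts of 19 and 5 cannot be told apart from that difference.

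Averaged over both media, no probe passed limma's test for the antibody, and 149 reached an unadjusted p under 0.05. Leaving out 1 array moved the 149 to between 67 and 668 (without replicates 4 and 3 of NQO1 after β-lapachone), and by over 1.5 times for 10 arrays. Array weights gave 10685 calls, a count that 28 of 100 relabellings reached. The probe leading the higher values was ILMN_2140990, with a log2 difference of 1.03 (SE 0.34, adjusted p = 0.988 by limma). It was detected on 2 of 4 IgG and 2 of 4 NQO1 arrays in control medium, and on 1 of 4 IgG and 4 of 4 NQO1 arrays after β-lapachone, so that the difference is taken against values mostly not above background. Its normalized intensity was 5.85 ± 0.74 in NQO1 and 5.16 ± 0.51 in IgG precipitates from control medium (log2, SD, n = 4 each), and 6.74 ± 0.31 against 5.38 ± 0.95 after β-lapachone (n = 4 each). Of the lower values, ILMN_1669669 led with a log2 difference of -0.93 (SE 0.22, adjusted p = 0.988 by limma). Its intensity was 4.97 ± 0.28 in NQO1 and 6.13 ± 0.43 in IgG precipitates in control medium (n = 4 each), and 5.39 ± 0.15 against 6.11 ± 0.50 after β-lapachone (n = 4 each). It was detected on 5 of the 8 NQO1 arrays and on 7 of the 8 IgG arrays. The undetected IgG value, on replicate 4 after β-lapachone, was 6.57 after normalization, above the detected ones of its group (5.40 to 6.31). The IgG mean after the drug thus includes a high value not above background. No probe of the table was detected on all 8 NQO1 arrays and on none of the 8 IgG arrays.

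Whether β-lapachone altered the enrichment by the anti-NQO1 antibody was tested as the difference of the NQO1 over IgG ratio between media. No probe passed limma's test, 55 reached an unadjusted p under 0.05 and the smallest adjusted p was 0.790. Leaving out 1 array moved the 55 to between 25 (without NQO1 replicate 1 after β-lapachone) and 322 (without IgG replicate 1 after β-lapachone), and by over 1.5 times for 14 arrays. Array weights gave 71 calls, a count that 61 of 100 relabellings reached. Of the 5 leading probes with a higher ratio after β-lapachone, 4 were detected in every group, with log2 differences of 1.04 to 1.93. Of the 5 with a lower ratio only 1 was, with a difference of -2.33.

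The effect of β-lapachone was then compared within each precipitate. In the NQO1 precipitates the mean profiles with and without the drug correlated at r = 0.969 across probes. No probe passed limma's test, 137 reached an unadjusted p under 0.05 and the smallest adjusted p was 1. Leaving out 1 array moved the 137 to between 61 and 371 (without replicates 2 and 3 of NQO1 after β-lapachone), by over 1.5 times for 8 arrays, and the smallest adjusted p by limma to as low as 0.370 (without IgG replicate 4 after β-lapachone). The leading probe with higher values was ILMN_1751120, at 7.15 ± 0.77 after β-lapachone and 4.76 ± 0.27 in control medium (log2, SD, n = 4 each). It was detected on all 4 arrays after the drug and on 1 of 4 without it. Its log2 difference was 2.39 (SE 0.42, adjusted p = 1 by limma), taken against control values mostly not above background. The leading 5 probes with lower values after the drug had log2 differences from -1.98 to -1.21.

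In the IgG precipitates, where no protein was targeted, the same probe led the higher values. ILMN_1751120 was detected on all 4 arrays after β-lapachone, at 7.74 ± 0.80 (log2, SD, n = 4), and on none of the 4 arrays in control medium. With the main processing it was at least 6.10-fold higher (adjusted p = 0.130 by limma). That bound depends on the processing, since without background correction the difference of the means was only 1.23 on the log2 scale. ILMN_2155719 led the lower values, with 4.94 ± 0.54 after the drug and 7.57 ± 0.73 in control medium (n = 4 each) and a log2 difference of -2.63 (SE 0.54, adjusted p = 0.892 by limma). It was detected on 1 of 4 arrays after the drug and on 4 of 4 in control medium. In the NQO1 precipitates it read 5.05 ± 0.31 after the drug and 6.33 ± 1.22 without it (n = 4 each). No probe passed limma's test in the IgG precipitates, and 289 reached an unadjusted p under 0.05. Leaving out 1 array moved the 289 to between 127 (without IgG replicate 4 in control medium) and 969 (without IgG replicate 3 after β-lapachone), and by over 1.5 times for 6 arrays. Without replicate 3 of the NQO1 precipitates after β-lapachone, 1 probe passed. The groups did not overlap for 217 probes in the IgG and 266 in the NQO1 precipitates, or 1.09% and 1.34% of those tested. Scaling each array by its z score gave 3 calls in each precipitate. With array weights there were 2803 in the NQO1 and 768 in the IgG precipitates, counts that 6 and 21 of 35 splits reached.

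**Figure D3:**
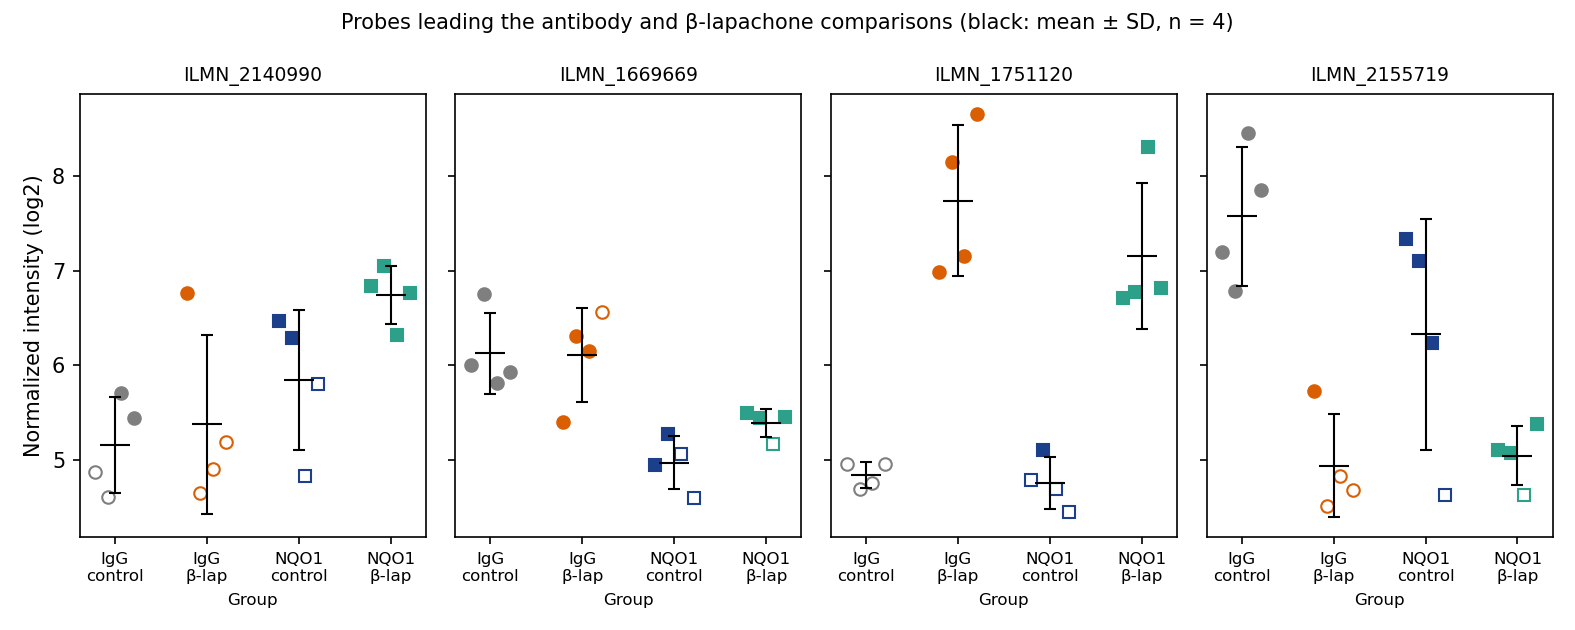
Normalized intensity (vertical axis, log2) of the 4 named probes on each array, by group (horizontal axis), with filled symbols where the probe was detected, open symbols where it was not, and the mean ± SD of 4 arrays in black. ILMN_1751120 lay at 6.71 or higher on the 8 arrays after β-lapachone and at 5.11 or lower on the 8 in control medium.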

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

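The test of the brightest probes, that of shared replicate numbers and that of the groups on the first component were chosen after the spread of the arrays had been seen. Of 32 groups of 4 arrays examined, over 4 array measures and the 4 named probes, 4 held an array whose gap to the nearest of the others exceeded Dixon's 95% critical value, where chance gives 1.6. Replicate 4 of the NQO1 precipitates in control medium had 33.6% of its intensity above the median in the 100 brightest probes, against 13.7% on the next array of its group. In another group, replicate 4 of the IgG precipitates after β-lapachone came near it with 29.1%. Replicate 3 of the NQO1 precipitates after β-lapachone was alone at 135 on the first principal component, with the nearest array of its group at -107. The same array read 8.30 on the log2 scale for ILMN_1751120, where the next of its group read 6.82. For ILMN_1669669 it read 5.17, where the next of its group read 5.44. For ILMN_1751120, replicate 4 of the IgG precipitates after β-lapachone read 8.66.

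The spread along the first component ran within every group, and 3 technical or design explanations were set against it. For less labelled RNA that lost only dim probes, the test cannot decide. On the 6 arrays with under 16000 detected probes, 19.8% of the 500 brightest probes (99 probes) lay over 2-fold lower. This share has no reference from other splits of the arrays. It was also taken after quantile normalization, which gives every array the same distribution of values. Less labelled RNA therefore stays open. A day or batch shared by equal replicate numbers was not shown. The mean correlation between the deviations of same-numbered arrays was -0.0499 (exact permutation p = 0.630, one-sided, over 13824 arrangements). Single pairs ran from -0.855 to 0.883, so such a batch is not excluded either. The antibody and the drug are argued against as its main source by the 11.7% of its variance that the groups held (exact permutation p = 0.638). RNA recovery or amplification that differed between single precipitates may account for it and was not tested.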

How the results depend on the processing

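The fits on 10 arrays, without 2 arrays and with covariates were chosen after seeing the data. In all 6 comparisons the count of calls stayed at 0 with median centring, no background correction, no detection filter, the stricter filter, the 8 arrays alone where this applied, and the replicate block (0 calls, 62 to 275 probes at an unadjusted p under 0.05 by limma). The 24 correlations between same-numbered arrays ran from -0.855 to 0.883, so the numbers were not taken to pair the arrays. Scaling by z score gave 3 calls for β-lapachone in the NQO1 and 3 in the IgG precipitates. Array weights gave 4740 calls for NQO1 against IgG in control medium, 8896 after β-lapachone, 10685 averaged and 71 for the difference of ratios. For β-lapachone they gave 2803 in the NQO1 and 768 in the IgG precipitates. The weights ran from 0.0611 to 13.5. In control medium, NQO1 replicate 2 (13.5) and IgG replicate 4 (13.4) held most of the weight of their groups. Leaving out each array in turn gave 0 to 0 calls in 5 comparisons and 0 to 1 for β-lapachone in the IgG precipitates, where the 1 call came without replicate 3 of the NQO1 precipitates after the drug. The 10 arrays with over 16000 detected probes gave 3 calls for β-lapachone in the NQO1 and 2 in the IgG precipitates. The covariate of detected probes gave 5 in the NQO1 precipitates, and 1, 2, 3 and 4 principal components gave 10, 36, 67 and 248 in the NQO1 and 6, 15, 55 and 157 in the IgG precipitates, with 0 calls in the other 4 comparisons. With 1, 2 and 3 components of the deviations from group means, which take spread within groups out of the error by construction, counts were 0, 736 and 2993 for NQO1 against IgG in control medium, 3921, 7351 and 9268 after β-lapachone, 0, 2102 and 5344 averaged, 2765, 6433 and 8294 for the difference of ratios, 127, 2490 and 4686 for β-lapachone in the NQO1 and 1980, 5987 and 7936 in the IgG precipitates. The cause of these differences was not tested beyond the relabelling tests. Without the 2 arrays under 10000 detected probes, 0 calls were made. Median centring moved the median of all probes to -0.38 for NQO1 against IgG after β-lapachone. The named probes kept their sign in the comparisons they led under every setting that tested them. ILMN_2140990 was not tested under the stricter filter. All settings reuse the arrays on which these probes were picked, so the kept signs are not independent support. Not run were the rule for several probes of a gene, which needs names, a slide block, since slides are not given in the sources used here, and the gene and gene list results. The column headers number each group in a consecutive run, with all IgG arrays before all NQO1 arrays. If these numbers follow an order of processing, its effect cannot be told apart from that of the antibody.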

Other observations

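The fits with components and on 10 arrays were chosen after seeing the data, while the checks of them on other arrays and on relabelled arrays were set before their outcome was seen, except that the allowance for counting error in the check of the antibody was added after it. Across all probes, the changes with β-lapachone in the NQO1 and IgG precipitates correlated at r = -0.386 on 16 arrays and at 0.599 on the 10 arrays with over 16000 detected probes. Probes are not independent replicates, and the mean score on the first principal component shifted with the drug by 79.9 in the IgG and by -55.6 in the NQO1 precipitates, so that this r does not bear on changes in a few probes. With the first 2 principal components of the 16 arrays held constant in limma, 36 probes were called in the NQO1 and 15 in the IgG precipitates, of which 13 were shared, all with the same direction. Averaged over both antibodies, 385 probes passed, 149 higher and 236 lower after the drug. ILMN_1751120 was among those higher (adjusted p = 0.000164 by limma), with no size given since it was not detected on any control IgG array. ILMN_2155719 fell by 1.90 on the log2 scale (SE 0.22, adjusted p = 0.000652 by limma). After the drug it was detected on 1 of 4 IgG and 3 of 4 NQO1 arrays, so that this size rests partly on values not above background. The components were taken from the same 16 arrays and take spread out of the error. A relabelling of medium gave 1086 calls in this fit, so these adjusted p-values may be too small. The number of components was picked after the counts were seen: the average gave 2 calls with none, 54 with 1, 461 with 3 and 1356 with 4. The antibody averaged over both media gave 0 calls by limma with 0 to 4 components, with 149, 602, 1201, 1598 and 1029 probes at an unadjusted p under 0.05. With 2 components of the deviations from group means, β-lapachone gave 626 calls and the antibody 2102.

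A hypothesis is that β-lapachone may have changed some RNAs within 30 min alike in both precipitates. Of 100 relabellings of medium within each precipitate, the real one included, 2 reached the 385 calls (highest other 1086, which points to structure among the arrays). The 13 shared calls were reached by 1 (highest other 0), and the 54 calls with 1 component by 1 (highest other 0). The 1356 with 4 components were reached by 1 (highest other 4). These lie under the share of 5% set in advance as counting against chance. The 461 with 3 components were reached by 6 (highest other 2800) and the 626 with components of the deviations by 74 (highest other 11172), which do not. Chance is not excluded across these fits, as the settings differ and 2 components were picked after the counts were seen. Without any covariate, 24 probes had all 4 drug arrays on the same side of the control arrays in both precipitates. By chance 8.13 (0.0408% of those tested) are expected on average, while the median of the other relabellings was 2. Of all 2450 relabellings, 105 (4.29%) gave as many, under the share of 5% set in advance as counting against chance. The highest other gave 1187, which points to structure among the arrays, so chance is not excluded for this count. Of 200 probes chosen on the 10 arrays with over 16000 detected probes, 39 were higher after the drug and the rest lower. On the 6 other arrays 88.5% went the same way, against at most 82.5% in the other labellings, of 20 in all. Among the 6, the drug arrays were IgG replicates 2 and 4 and NQO1 replicate 3. The control arrays were IgG replicate 2 and NQO1 replicates 3 and 4, so the antibody is not balanced between the media. The 88.5% lies between the bounds of 75 and 90% set in advance, so a part played by the gradient of detected probes stays open.

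For the antibody, the NQO1 over IgG ratios of the 2 media correlated across probes at r = -0.209 on 16 arrays and at 0.871 on the 10 arrays. The ratio in one medium correlated on average at 0.463 with the difference between IgG arrays of many and of few detected probes in the other medium, so the gradient of detected probes may account for part of it and stays open. Of 200 probes chosen on the 10 arrays, 35 were higher in the NQO1 precipitates and the rest lower. On the 6 other arrays, which do not balance the media between the antibodies, 73.5% went the same way. Its counting SE of 3.12 takes the probes as independent, which they are not. The other labellings, of 20 in all, gave at most 67.0%. The 73.5% lies under the 75% set in advance as counting against RNA bound to NQO1, with 90% set as what such RNA would give. It does so by less than that SE. As most of these probes were lower with the anti-NQO1 antibody, the check cannot decide on RNA bound to NQO1. Such RNA is not excluded and is not separated from the gradient of detected probes. In both media alike, 3 probes were parted by antibody, and 814 of 2450 relabellings gave as many, with 5500 as the highest other, which again points to structure among the arrays.

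A count of 0 calls is reached by every split by construction, 35 of 35 for each comparison of 2 groups and 100 of 100 for the average, for the difference of ratios and for the antibody average with 2 principal components (highest other 860), so these counts say nothing about chance. Among the 6 planned comparisons, the highest other split gave 0 calls for NQO1 against IgG in control medium, 6847 after β-lapachone, 4393 for the average, 1 for the difference of ratios and 0 for β-lapachone in each precipitate. The split with 6847 calls points to a structure of the arrays. With array weights, as many calls as the real 4740, 8896, 2803 and 768 came from 21, 11, 6 and 21 of the 35 splits, with 15255, 14480, 14125 and 12106 as the highest others, in the order NQO1 against IgG in control medium, after β-lapachone, and β-lapachone in the NQO1 and IgG precipitates. For the average, 28 of 100 splits reached the real 10685 calls (highest other 16015), and for the difference of ratios 61 of 100 reached 71 (highest other 13656). Chance was not excluded for any count of calls made with array weights.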
